A study of Danio rerio with 2 samples.

How the data were processed

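RNA was taken from dissected, flash-frozen zebrafish hearts at 96 hours post fertilisation, per the labels' protocols, and sequenced as 1 library of foxc1a nju18 fish and 1 of wild-type TU fish. Groups were taken from the genotype label of each sample. The submitters' processing notes name bcl2fastq, Trimmomatic, HISAT2, featureCounts and the genome build GRCz11, with no versions, roles or order. Settings of the counting, such as strand or the treatment of reads that fit several places, were not given in the sources used here, so overlapping genes and near-identical copies are uncertain.

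The authors deposited a raw count per Ensembl gene for each library. The deposited FPKM values equalled the count divided by the library's total count and by 1 whole-number length per gene (within 0.01 for 100% of genes), with the same length in both libraries for 21662 genes with reads in both, so they carry the same information as total-count scaling. The authors' deposited comparison table holds a normalised signal per library, which equalled the deposited count divided by a size factor of 0.854 for the mutant-labelled library and 1.17 for the wild-type-labelled library. Its fold change is a ratio of these values with 0.01 added to each, and its log2 column is the log2 of that ratio, as tested on the deposited values. Its FDR column holds the authors' false discovery rate, per the file headers. It is used here with their threshold and, as an alternative, with a stricter one of 0.01, as a q-value would be. All of the authors' calls had an FDR below 0.05 (largest 0.0499). The table is named for EBSeq, an empirical Bayes method that works with posterior probabilities; how the FDR was derived and how EBSeq was run on 1 library per group was not given in the sources used here. Genes with 2 or fewer reads over both libraries are absent from that table, and the smallest absolute log2 fold change among the authors' calls was 1.51.

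The deposited counts were used for the main comparison. Library totals were 17467109 (mutant-labelled) and 20049851 (wild-type-labelled) and were scaled with TMM factors of 0.904 and 1.11 from edgeR 4.0.16 in R 4.3.3. Log2 ratios are mutant-labelled minus wild-type-labelled, of CPM with 1 CPM added to each, which understates differences of low genes. Printed ratios have nothing added. Genes at 5 CPM or more in either library (12259 of 25254 with a read) were described, and 2-fold on the log2 scale was the fixed rule of size in place of a test, since 1 library per genotype leaves no spread between replicates. Exact 95% Clopper-Pearson intervals of each ratio came from the conditional binomial of its reads (scipy 1.17.1, Python 3.11.15). Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only and are too narrow for any statement on genotypes.

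There were 43 gene lists (heart, vessel, blood, signalling, metabolism, stress and other tissues), fixed before the data were examined, with the rule for named genes. That rule takes foxc1a and foxc1b, the 12 genes with the largest log2 ratio in each direction among genes with a name rather than a clone-based or numbered placeholder, up to 4 measured members per list with the largest absolute log2 ratio, a fixed set of heart genes and the 5 genes with the most reads per library. Of all list members, 24 symbols matched no gene. In the whole count table, 382 symbols stood for more than 1 gene. For each list the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The gonad and germ cell list had under 3 measured members and was left out, leaving 42. A median outside the 2.5th to 97.5th percentile is called outside the random range, a range chosen after the medians had been seen. About 2.1 of 42 lists would lie outside it by chance if genes were independent, which members of a list are not, so percentiles describe these libraries only.

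The alternatives planned before the data were examined were total-count scaling, DESeq2 1.42.0 size factors, 0.25 or 5 CPM added, no expression filter or a filter of 20 CPM, the deposited FPKM with 1 FPKM added, a total without genes over 1% of a library, 1.5-fold and 4-fold rules, means in place of medians, members on no other list, and a stricter FDR of 0.01 or an added 2-fold rule for the authors' calls. Protein-coding genes without mitochondrial ones, and genes on no list of another tissue, were added after seeing the data. The scripts were tested on simulated counts for the comparison of the mutant-labelled with the wild-type-labelled library. Over 11566 simulated genes, 100% of 4-fold changed genes passed the rule in each direction (200 genes changed), 0 of 11336 unchanged genes did, and 95.3% of unchanged genes had an interval that held 1. The simulated counts varied by counting (Poisson) error alone, with no variation between animals or libraries. They check the scripts and do not give the rate of false calls between real libraries. A simulated list of 30 genes shifted 2-fold gave a median of 0.98 at percentile 100, and an unshifted list gave 0.03 at percentile 90.5. Gene order for the neighbours of foxc1a came from a RefSeq table on the assembly GRCz12tu, joined by Entrez identifier for 11483 genes (93.7% of those at 5 CPM or more). Coordinates were not used, since that assembly differs from the authors' build. Tables and plots were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.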

Results

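Gene expression was measured by RNA sequencing in dissected hearts of zebrafish (Danio rerio) at 96 hours post fertilisation. One library came from fish carrying the nju18 allele of foxc1a, a forkhead transcription factor gene active in mesoderm and neural crest derivatives, and the other from wild-type fish of the TU strain. The design therefore asked how cardiac gene expression differed between the foxc1a genotype and wild type, with 1 library per genotype. The number of hearts behind each library was not given in the sources used here. The count table held 32057 genes, with 17467109 reads counted to genes in the mutant-labelled library and 20049851 in the wild-type-labelled library. At least 1 read was found for 22795 and 24121 genes, respectively. With no replicate libraries, no difference below has a replicate check and no test was made between genotypes. The 95% counting intervals are exact (Clopper-Pearson), cover counting error only, and compare these 2 libraries rather than the genotypes.

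The targeted gene was present in both libraries and was higher in the one labelled mutant. foxc1a (ENSDARG00000091481) had 798 reads in the mutant-labelled library and 629 in the wild-type-labelled library, or 50.5 and 28.4 CPM after TMM scaling, a ratio of 1.78 (counting interval 1.60 to 1.98). Its paralog foxc1b (ENSDARG00000055398) had 48.7 and 75.6 CPM, a ratio of 0.644 (counting interval 0.590 to 0.702). The authors' deposited table called neither gene different, with a log2 fold change of 0.80 (FDR 0.819) for foxc1a and -0.67 (FDR 0.904) for foxc1b. What the allele does to the transcript is not stated in the labels, and gene counts do not show a small sequence change. The level of foxc1a therefore did not check the labels, and the libraries are called mutant-labelled and wild-type-labelled throughout, directions being those of the labels.

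Muscle myosin genes were among the genes with the largest positive log2 ratios, and cone opsin genes among those with the largest negative ones. Among 12259 genes at 5 CPM or more in either library, 1178 were at least 2-fold higher in the mutant-labelled library and 1358 at least 2-fold lower, 20.7% of genes together. The counting interval of the ratio lay wholly beyond 2-fold for 903 of the genes at 5 CPM or more in the higher direction and 1027 in the lower direction. Of the 2-fold genes, 46.5% were higher with TMM scaling. With total-count scaling the split was 702 higher and 2166 lower (24.5% higher), and with a total that left out the 7 genes over 1% of a library it was 777 and 2252 (25.7% higher). Total-count scaling moved log2 ratios by -0.29, and the median of all genes was 0.04 with TMM and -0.26 with total-count scaling. Values below are relative to TMM scaling, so small positive log2 ratios, up to about 0.29, can have the opposite sign with total-count scaling.

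**Figure D1:**
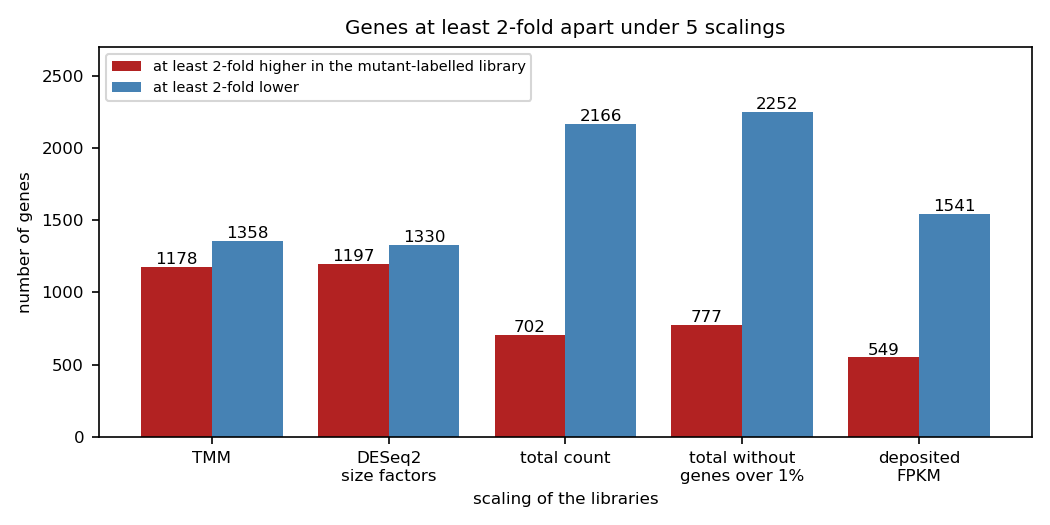
Numbers of genes at least 2-fold higher (red) and at least 2-fold lower (blue) in the mutant-labelled library under 5 scalings, with 1 library per genotype. The split was 1178 to 1358 with TMM and 702 to 2166 with total-count scaling, and 549 to 1541 with the deposited FPKM, which also rest on the total count.

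The 12 named genes with the largest positive log2 ratios included fast skeletal myosin heavy chains, with myhz1.2 at the top and myhz1.1 after nupr1b and aqp8a.2. myhz1.2 had 1986 CPM in the mutant-labelled library and 36.6 CPM in the other (log2 ratio 5.72), and myhz1.1 had 3397 and 136 CPM (4.63). myh7, the ventricular myosin heavy chain gene of zebrafish, stood at 6535 against 621 CPM, a ratio of 10.5 (counting interval 10.3 to 10.7). These myosin genes lie among near-identical copies, so the division of reads between copies is uncertain. nupr1b, a stress-responsive nuclear protein gene, had 772 and 9 reads, a ratio of 120 (counting interval 63.1 to 264). The other genes of this group were the aquaporin gene aqp8a.2 (log2 ratio 4.65), the complement gene c4b (3.51), bin2a (3.40), the organic anion transporter gene slco1d1 (3.39), plxdc1 (3.38), the carbonic anhydrase gene ca4b (3.33), the versican gene vcana (3.28) and igf1rb (3.19), an insulin-like growth factor receptor gene.

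Cone opsins and other retinal genes made up much of the opposite end. Among the 12 named genes with the largest negative log2 ratios, opn1sw2, opn1sw1 and opn1mw1, which encode cone visual pigments, were lower in the mutant-labelled library by 22.4, 12 and 10.5 times. The lens crystallin gene crygm2d1 had 19.9 against 403 CPM (log2 ratio -4.27), and it shares sequence with close copies. prph2b, which encodes a protein of photoreceptor discs, and the retinal gene lrit1a had log2 ratios of -3.36 and -3.77. The synaptic vesicle gene sypa stood at -3.36. fabp6, an intestinal bile acid binding protein gene, had 4.62 against 70.4 CPM, and rhcga, which encodes an ammonium transporter, had 22.7 against 254 CPM. The serine protease gene prss60.2 (-4.01) and the nucleoside diphosphate kinase gene nme2a (-3.33) completed this end apart from ankrd1b, a stretch-responsive gene of striated muscle. ankrd1b had 2 reads against 345, a ratio of 0.00814 (counting interval 0.000982 to 0.0296), in the direction opposite to most muscle genes.

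Genes of the cardiac sarcomere list were higher in the mutant-labelled library as a group. The list was not limited to genes that only the heart uses, so its values do not separate heart from skeletal muscle. Of 30 measured cardiac sarcomere genes, 19 were at least 2-fold higher and 0 at least 2-fold lower, and the list's median log2 ratio of 1.25 lay at percentile 100 of 10000 random lists matched on expression. tnnt2a, cardiac troponin T, had 2213 and 495 CPM, myh7l had 7644 and 1485 CPM, and desmb had 11 and 0.992 CPM. myl7, the myosin light chain gene common to both chambers, had 4383 and 2608 CPM, a ratio of 1.68. Sarcomere list genes took 3.40% of reads in the mutant-labelled library and 1.39% in the other. Skeletal muscle genes moved with them: 31 of 40 were at least 2-fold higher and 0 lower, with a median of 1.68 (percentile 100) and 2.66% against 0.872% of reads.

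Further lists of cardiomyocyte genes, some with members also on other lists, had medians above the random range. The skeletal muscle list had a larger median, 1.68. Chamber identity genes (8 measured, of which 6 were also on other lists) had a median of 0.84 (percentile 99.6), with nppa at 3961 and 1200 CPM, and myh6, the atrial myosin heavy chain, at 43.6 and 26.2 CPM. The alternative without members of other lists left too few chamber identity genes to be run. Calcium handling and excitability genes had a median of 0.97 (percentile 100), and 8 of 16 were at least 2-fold higher and 0 lower. In this list kcnh6a, a repolarising potassium channel gene, was 3.82 times higher, jph2 3.86 times and trdn 3.68 times, the last 2 encoding proteins of the calcium release unit. With no expression filter the list's median was 0.12 and lay within the random range. Cardiac load genes had a median of 0.92 (percentile 99.9), with 4 of 11 at least 2-fold higher and 1 lower. nppb, a natriuretic peptide gene, had 593 and 259 CPM, nppc 42.8 and 8.16 CPM, and xirp1 308 and 88.7 CPM, while ankrd1b was the lower member. The load list lay within the random range as a mean (0.38) and without members of other lists (0.63).

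Cardiac transcription factor genes were mostly higher in the mutant-labelled library, 16 of 19 with a log2 ratio above 0 under TMM scaling and 12 under total-count scaling. Their median was 0.51 (percentile 99.03), and 2 were at least 2-fold higher and 2 lower. nkx2.7 had 17.8 against 5.77 CPM and gata6 88.9 against 43.3 CPM, whereas isl1, which marks progenitors of the second heart field and also neurons, had 3.99 against 23.0 CPM and srfa 5.13 against 13.7 CPM. tbx5a stood at 14.9 and 7.89 CPM, nkx2.5 at 17.8 and 14.6 CPM, hand2 at 137 and 112 CPM, and gata4 at 5.19 and 4.83 CPM. The list's median lay within the random range with the 20 CPM filter (0.52), with the total that left out genes over 1% (0.15), over protein-coding genes (0.41) and as a mean (0.28).

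Endothelial, valve and epicardial genes had medians within the range of random lists. The endothelium and endocardium list (21 genes) had a median of 0.24 (percentile 82.5), with 0 genes at least 2-fold higher and 1 lower, the tight junction gene cldn5b at 56.0 against 171 CPM. kdrl, a vascular growth factor receptor gene, had 79.4 and 73.8 CPM, a ratio of 1.08 (counting interval 0.999 to 1.16). Of 23 valve and cushion genes, 4 were at least 2-fold higher and 4 lower (median 0.09, percentile 47.0). vcana was 10.8 times higher and dll4, a Notch ligand gene, 4.49 times higher, while wnt9b was 5.44 times lower and cspg4 4.19 times lower. klf2a, a flow-responsive transcription factor gene, had 25.6 and 24.2 CPM, has2 36.0 and 26.1 CPM, and bmp4 28.9 and 24.4 CPM. Among 11 epicardial genes (median -0.21, percentile 17.3), the transcription factor genes tbx18 (3.93 and 13.6 CPM) and tcf21 (3.04 and 10.4 CPM) were lower and sema3fb was higher (19.4 and 6.31 CPM), and aldh1a2 had 17.5 and 10.6 CPM. The epicardial median was 0.25 over 5 genes with the 20 CPM filter and 0.00 over 12 genes with no filter, so its sign is not firm. The lymphatic list of 7 genes had a median of 0.33 (percentile 80.3), and 0 of its genes were 2-fold apart. The medians of the endothelial and valve lists change sign with total-count scaling. The lymphatic median was -0.08 there, but over the 4 genes that then passed the expression filter.

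Smooth muscle, matrix, and cartilage and bone lists had medians below the random range, and the neural crest list lay within it. Of 15 smooth muscle and outflow tract genes, 2 were at least 2-fold lower and 0 higher (median -0.37, percentile 1.58): the elastin gene elnb (199 and 470 CPM) and pdgfrb (31.2 and 68.9 CPM). acta2, smooth muscle actin, had 280 and 232 CPM. That list's median lay within the random range with 5 CPM added (-0.27), as a mean (-0.24), with the deposited FPKM (-0.57) and without members of other lists (-0.30). Of 28 fibrillar and basement matrix genes, 3 were lower and 0 higher (median -0.16, percentile 0.52), among them the collagen genes col5a2b (7.47 and 22.3 CPM) and col4a1 (37.7 and 86.0 CPM), and the list lay within the random range with the deposited FPKM (-0.38). Cartilage and bone genes had 6 of 25 at least 2-fold lower and 0 higher (median -0.38, percentile 0.035), with col10a1a at 158 and 798 CPM. Neural crest and pigment genes had a median of -0.07 (percentile 43.8), and 1 of 11, tfap2b, was at least 2-fold lower (2.72 and 16.4 CPM).

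**Figure D2:**
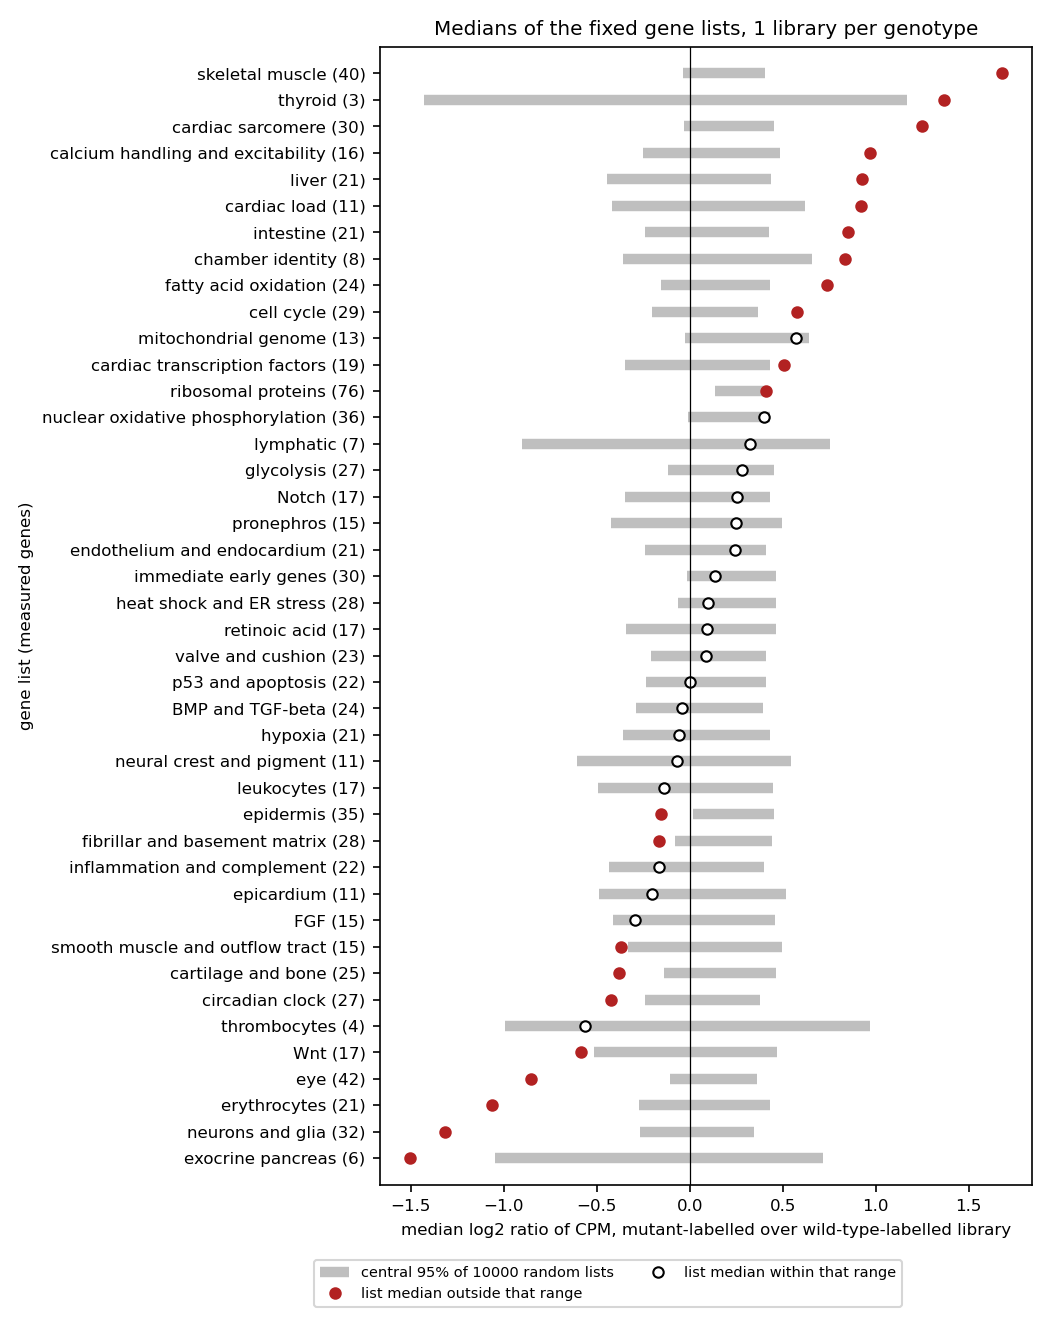
Median log2 ratio of TMM-scaled CPM, mutant-labelled over wild-type-labelled library, for 42 gene lists (circles, measured genes in brackets), with 1 library per genotype; grey bars span the central 95% of medians of 10000 random lists matched on size and expression. Filled circles are the 22 lists outside their bar, 12 above it (skeletal muscle at 1.68, cardiac sarcomere at 1.25) and 10 below it (neurons and glia at -1.32, exocrine pancreas at -1.51 over 6 genes).

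Signalling lists mostly lay within the random range. Wnt genes had a median of -0.58 (percentile 1.31), with 4 of 17 at least 2-fold lower, among them wnt9b, tcf7 and notum1a (2.03 and 6.67 CPM), and 1 higher, sfrp5, a secreted Wnt antagonist gene (86.6 and 26.5 CPM). The Wnt list lay within the random range with the 20 CPM filter (-0.10), with no filter (-0.31), with 5 CPM added (-0.37) and as a mean (-0.46). Notch genes had a median of 0.26 (percentile 84.0) with 3 of 17 higher and 1 lower. notch1b had 38.5 and 50.1 CPM and rbpja, which encodes the DNA-binding partner of Notch, 13.5 and 28.6 CPM. BMP and TGF-beta genes had a median of -0.04 (percentile 29.9), and 1 of 24 was higher (id3, 430 and 167 CPM) and 3 lower (bmpr2a, bmpr2b and bmp2a). The FGF list stood at -0.29 (percentile 6.96), with 2 of 15 lower (fgfr1b and spred1). Retinoic acid genes had a median of 0.09 (percentile 54.4) and a mean of -0.06. dhrs3b, a retinaldehyde reductase gene, was the 1 of 17 that was at least 2-fold higher (51.2 and 15.2 CPM), and crabp2a (6.97 and 28.2 CPM) and rbp4 (366 and 957 CPM) were lower. With the 20 CPM filter the retinoic acid median was -0.76, below the random range. The Notch and retinoic acid medians change sign with total-count scaling.

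Proliferation and oxidative metabolism genes had positive medians, in the same direction as the skeletal muscle (1.68) and cardiac sarcomere (1.25) lists. The libraries also differed in their share of nuclear ribosomal RNA reads, 0.0436% in the mutant-labelled and 0.485% in the wild-type-labelled library. Of 29 cell cycle genes, 4 were at least 2-fold higher and 0 lower (median 0.58, percentile 99.96), including ccne2 (36.9 and 11 CPM), aurka (48.3 and 16.7 CPM) and mcm2 (113 and 53.9 CPM). Fatty acid oxidation genes had a median of 0.74 (percentile 99.97), with 4 of 24 higher and 0 lower, such as acadl (32.8 and 11.8 CPM) and cd36 (60.0 and 22.8 CPM). The nuclear oxidative phosphorylation list stood at 0.40 (percentile 95.4), within the random range, though its mean of 0.51 lay above it. In that list 3 of 36 genes were higher, led by the mitochondrial ADP/ATP carrier gene slc25a4 with 381 against 40 reads. The 13 genes of the mitochondrial genome had a median of 0.57 (percentile 94.98), also within the random range, and took 12.6% and 10.6% of reads. Glycolysis genes had a median of 0.28 (percentile 80.3), 7 of 27 higher and 1 lower, the last being the glucose transporter gene slc2a3a (6.40 and 38.7 CPM), and this median changes sign with total-count scaling. Ribosomal protein genes had a median of 0.41 (percentile 98.0), with 1 of 76 higher and 0 lower, and lay within the random range with the 20 CPM filter (0.41) and as a mean (0.35). The symbol pattern of this list also took 8 genes of kinases, binding proteins and ribosomal-protein-like genes, among them the higher one, rps6ka1.

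Stress lists gave no median outside the random range. p53 and apoptosis genes stood at 0.00 (percentile 30.4), with ccng1 higher (185 and 74.7 CPM) and phlda3 lower (22.6 and 48.5 CPM). Hypoxia genes stood at -0.06 (percentile 30.7), with 2 of 21 at least 2-fold higher and 3 lower. Heat shock and ER stress genes had a median of 0.10 (percentile 21.1) and a mean of -0.02, and the inducible chaperone genes hsp70.3 (255 and 825 CPM) and hsp70.2 (157 and 424 CPM) were lower while the constitutive hspa8 was higher (462 and 192 CPM). Immediate early genes had a median of 0.14 (percentile 22.4) and a mean of -0.04, with 2 of 30 higher and 3 lower. Both of these medians change sign with total-count scaling. The circadian clock list lay below the random range at -0.42 (percentile 0.11), and 7 of 27 genes were at least 2-fold lower and 0 higher. The neurons and glia (-1.32) and eye (-0.85) lists lay below it too. per1a had 4.50 and 31.0 CPM and the clock-output gene hlfa 30.3 and 91.5 CPM. Inflammation and complement genes went both ways, with 5 of 22 higher and 8 lower (median -0.17, percentile 23.0). The matrix metalloproteinase genes mmp13a (9.69 and 74.5 CPM) and mmp9 (24.4 and 115 CPM) were lower, and the acute phase gene saa (15.2 and 1.98 CPM) and the complement gene c6 were higher.

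Red cell genes were lower, with 12 of 21 at least 2-fold lower and 1 higher (median -1.06, percentile 0), and all 8 measured globin genes were lower, 7 of them by 2-fold or more. hbae3 had 270 and 935 CPM and hbbe1.1 had 426 and 1239 CPM. The list took 0.159% of reads in the mutant-labelled library and 0.430% in the other. Leukocyte genes had a median of -0.14 (percentile 33.0), with 1 of 17 higher and 1 lower, the latter the neutrophil peroxidase gene mpx (7.16 and 18.1 CPM). The 4 thrombocyte genes had a median of -0.57 (percentile 12.3).

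Genes typical of other organs were measured in both libraries and also differed. In the wild-type-labelled library the eye list (1.47% of reads) and the epidermis list (2.48%) each took more reads than the cardiac sarcomere list (1.39%). Their shares in the mutant-labelled library were 0.918%, 2.77% and 3.40%, in that order. Values of genes that several tissues use therefore cannot be assigned to the heart alone. Neuronal and glial genes were lower, with 17 of 32 at least 2-fold lower and 1 higher (median -1.32, percentile 0), and gad2, which encodes an enzyme of GABA synthesis, had 6.46 and 39.9 CPM. Eye genes had 20 of 42 lower and 2 higher (median -0.85, percentile 0). Exocrine pancreas genes had 4 of 6 lower and 0 higher (median -1.51, percentile 0.13), with the trypsin gene prss1 at 6.02 and 18.9 CPM. Among the 6, prss59.1, prss59.2 and ela3l reached 5 CPM only in the wild-type-labelled library. With no expression filter the exocrine pancreas median was -0.48 over 22 genes (percentile 0.58), smaller in size but still below the random range. Epidermal genes had 7 of 35 lower and 3 higher (median -0.15, percentile 0.04). In the opposite direction, 8 of 21 liver genes were at least 2-fold higher and 4 lower (median 0.93, percentile 100), although the list's share of reads was 0.147% against 0.174%. The apolipoprotein genes apoc2 (209 and 32.2 CPM) and apoa1b (242 and 63.7 CPM) were higher, while apoea was lower, with 2 against 195 reads. Intestinal genes had 9 of 21 higher and 4 lower (median 0.85, percentile 100). cdx1b, an intestinal transcription factor gene, had 56.9 and 10.9 CPM, while fabp6 was lower, at 4.62 and 70.4 CPM. Pronephros genes had a median of 0.25 (percentile 81.2), a sign that turns with total-count scaling, and the 3 thyroid genes a median of 1.36 (percentile 98.8). The thyroid median was -0.13 with no expression filter, and lay within the random range with 5 CPM added (0.73), without genes over 1% (0.40) and over protein-coding genes (0.64). The gonad and germ cell list had under 3 measured genes and was given no median.

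**Figure D3:**
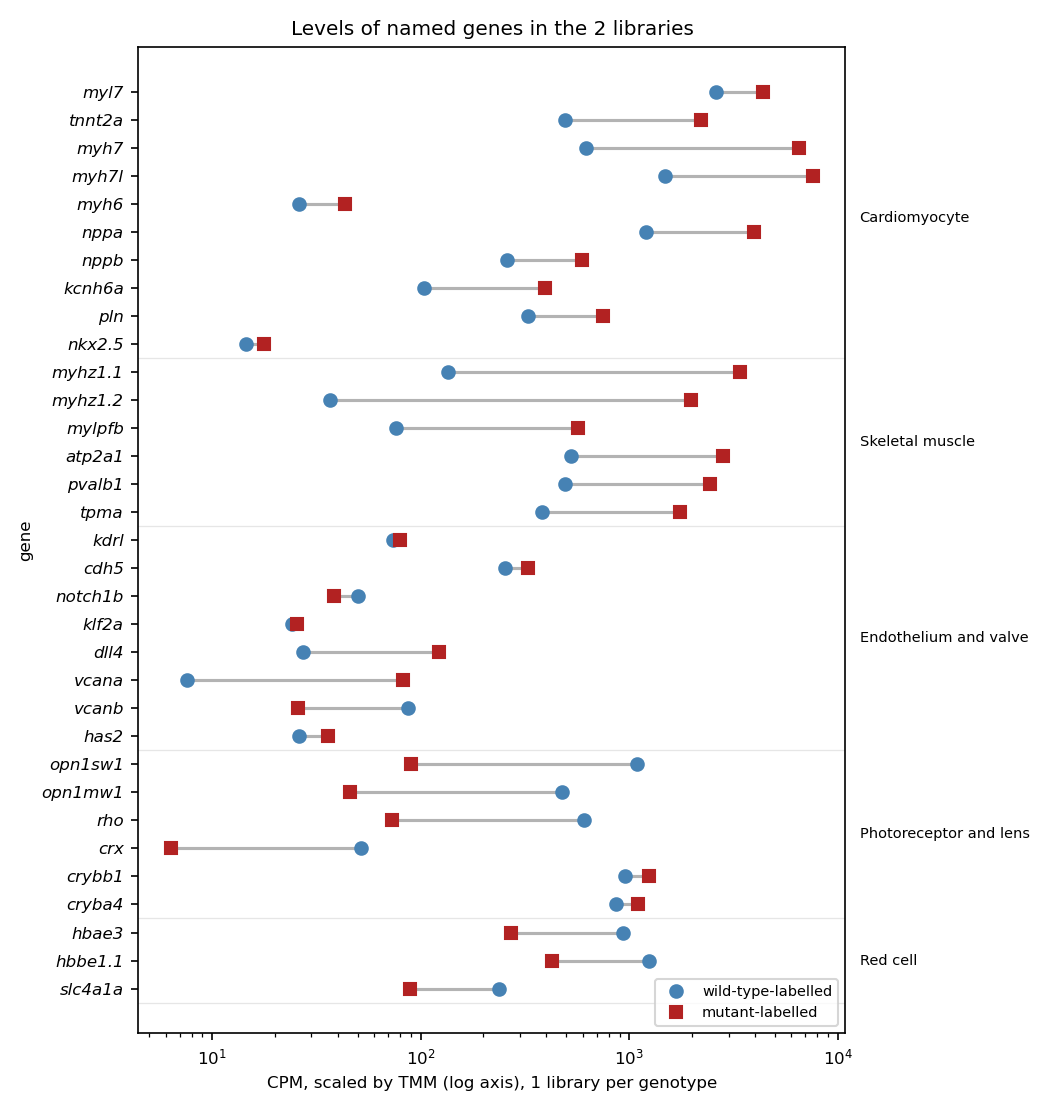
TMM-scaled CPM (log axis) of genes of 5 tissue groups in the mutant-labelled (red squares) and wild-type-labelled (blue circles) libraries, 1 library each, a grey line joining the 2 values of a gene; genes were chosen for display after their values were seen. myhz1.2 lay at 1986 and 36.6 CPM and opn1sw1 at 90.2 and 1087 CPM, while kdrl lay at 79.4 and 73.8 CPM, a difference that changes sign with total-count scaling, as do those of klf2a and nkx2.5.

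The authors' own comparison called more genes lower than higher. The authors' deposited table listed 23256 genes and called 987 UP and 1774 DOWN in the mutant-labelled library at an FDR below 0.05. Among genes at 5 CPM or more here, the authors' deposited table called 519 UP and 772 DOWN, and every one of these was also at least 2-fold apart here in the same direction. Both comparisons rest on the same counts, and the smallest absolute log2 fold change among the authors' calls was 1.51. This overlap was therefore largely fixed in advance and is no independent check. The remaining 468 UP and 1002 DOWN calls in the authors' deposited table were of genes below 5 CPM in both libraries. By list, the authors' deposited table called 21 skeletal muscle, 9 cardiac sarcomere and 9 intestinal genes UP, and 17 eye and 12 neuronal and glial genes DOWN. In the authors' deposited table nppa, nppb and myl7 were not called.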

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

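Gene and list alternatives were planned, except the sets of protein-coding genes and of genes on no list of another tissue, which were chosen after seeing the data; the cause of a shift was not tested unless the setting itself shows it. No paired analysis was possible because each genotype has 1 library, and no library could be left out. For genes at least 2-fold apart (2536, with 1178 higher and 1358 lower), total-count scaling gave 702 higher and 2166 lower, the total without genes over 1% gave 777 and 2252, and the deposited FPKM gave 549 higher. With 5 CPM added, which shrinks low genes, there were 1380 (719 higher, 661 lower). A 20 CPM filter, which tests fewer genes, left 1203 (695 and 508), and no filter gave 2108 lower. By construction a 1.5-fold rule gave more, 5371 (2733 and 2638), and a 4-fold rule fewer, 433 (178 and 255). DESeq2 size factors gave 1197 and 1330. Genes at least 2-fold apart beyond counting error (903 higher, 1027 lower) numbered 523 and 1662 with total-count scaling, 563 and 1688 without genes over 1%, 1366 and 1856 with no filter, and 562 and 404 with the 20 CPM filter. The sets added later gave 1235 higher and 1447 lower (protein-coding) and 1119 and 1294 (no other tissue's list). Of the authors' calls, 630 UP and 1090 DOWN had an FDR of 0.01 or less, and an added 2-fold rule removed none. The latter was fixed in advance, since the smallest absolute log2 fold change among the calls was 1.51.

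Of 456 list medians under alternatives, 432 kept their place within, above or below the random range, and 14 lists stayed outside it in every alternative run. A change of scaling moves nearly all log2 ratios by about the same amount, those of random lists included. The scaling alternatives could therefore hardly move a list's place, except through the genes that passed the filter, and the tally overstates how far places were tested. Filters changed the sign of some medians within the range. Among them were epicardium (0.25), leukocytes (0.29) and BMP and TGF-beta (0.13) with the 20 CPM filter, and Notch (-0.03) and retinoic acid (-0.08) with no filter. With total-count scaling, 9 medians within the range changed sign, the lymphatic one with 4 in place of 7 measured genes. Lists that moved within it were, with 5 CPM added, smooth muscle and outflow tract (-0.27), Wnt (-0.37) and thyroid (0.73); with no filter, calcium handling and excitability (0.12), Wnt (-0.31) and thyroid, which changed sign (-0.13); with the 20 CPM filter, cardiac transcription factors (0.52), Wnt (-0.10) and ribosomal proteins (0.41). FPKM moved smooth muscle and outflow tract (-0.57) and fibrillar and basement matrix (-0.38). Leaving out genes over 1% moved cardiac transcription factors (0.15) and thyroid (0.40), and the protein-coding set moved the same lists (0.41 and 0.64). As means, cardiac transcription factors (0.28), cardiac load (0.38), smooth muscle and outflow tract (-0.24), Wnt (-0.46) and ribosomal proteins (0.35) lay within the range. Without members of other lists, so did cardiac load (0.63) and smooth muscle and outflow tract (-0.30). Retinoic acid (-0.76, 20 CPM filter) and nuclear oxidative phosphorylation (0.51, mean) moved outside it. For foxc1a the log2 ratio of 0.81 became 0.53 with total-count scaling, 0.51 with FPKM and 0.55 without genes over 1%. Of 1182 values of 197 named genes, 539 moved beyond the counting interval. Depth limits low genes most: ankrd1b, with 2 reads in 1 library, has a ratio known only to between 0.000982 and 0.0296.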

Other observations

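The tests on the cardiomyocyte, photoreceptor, lens and neuronal sets, and the use of the split of higher and lower genes as a test, were chosen after the results had been seen; the scalings behind that split were planned, and the tests on further skeletal muscle genes and on genes near foxc1a were added after the patterns were seen and set before their own values were read. All use the same 2 libraries. Most measured nuclear ribosomal RNA genes were about 10 times or more lower in the mutant-labelled library, with RF00002 an exception at a ratio of 0.716. Nuclear ribosomal RNA genes took 7609 reads there (0.0436% of the library) against 97185 (0.485%), mostly from zgc:158463 with 6742 against 94163. Mitochondrial ribosomal RNA differed less and took 1.36% against 2.28%, while RF00017, a signal recognition particle RNA gene, had 415 against 9841 reads. With 1 library per genotype, these differences cannot be told apart from differences in how the 2 libraries were made, which was not tested. The ribosomal RNA genes and RF00017, and the genes of the next sentence, were named after their values were seen. Among genes with placeholder names, BX537263.3 had 92 against 13069 reads and its neighbour in name BX537263.4 had 52 against 6207, while si:dkey-15j16.6 had 182 against 2 reads.

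The actinodin genes and1, and2 and and3, which encode structural proteins of fin fold rays, were lower in the mutant-labelled library by 3.88, 7.48 and 4.33 times, while cyt1l, an epidermal keratin gene, was 3.95 times higher (3441 and 870 CPM). Of genes at 5 CPM or more, 9 had 3 or fewer reads in the mutant-labelled library and 2 had so few in the wild-type-labelled library. Genes with higher expression had higher log2 ratios: the median was 0.21 over 1649 genes at 100 CPM or more and 0.45 over 173 genes at 1000 CPM or more, with TMM scaling, beside 0.04 over all genes. Across genes, log2 CPM of the libraries had a Pearson r of 0.881, genes not being independent replicates.

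Muscle genes were higher in the mutant-labelled library. A larger amount of skeletal muscle beside the heart is a candidate explanation for the skeletal muscle genes, with myhz1.1 at 3397 against 136 CPM: 33 further skeletal muscle genes on none of the lists, some of which the heart also expresses, had a median log2 ratio of 0.83 (percentile 100), with 12 at least 2-fold higher, 1 at least 2-fold lower and 5 not higher. Their upper quartile of 1.21 lay below the median of 1.68 of the skeletal muscle list, so whether tissue amount accounts for the full size stays open. More skeletal muscle is not enough for 15 genes chosen as restricted to cardiomyocytes, if that restriction holds. Their median log2 ratio was 1.19, and 0 of the 15 were lower with TMM scaling (the smallest log2 ratio, 0.27, turns negative with total-count scaling). All 15 are members of the lists already described and were picked after those lists' values had been seen. The set therefore does not speak for the other cardiac genes. A larger share of cardiomyocytes stays open, since the log2 ratios of these genes had an SD of 0.84 and no replicate shows how much of that is noise. A difference in expression due to the genotype was not tested and cannot be told apart from this.

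Photoreceptor genes were lower in the mutant-labelled library, with a median log2 ratio of -2.58 over 15 genes, 14 of them at least 2-fold lower. All 15, and all 25 lens genes below, are members of the lists already described, whose values had been seen. Less whole-eye tissue in that library, as the whole cause, would lower lens genes as much, but the median of 25 lens genes was -0.19 (4 at least 2-fold lower, crygm2d1 among them, and 2 higher), which lay below its own random range (percentile 0.87) but is 2.395 above that of the photoreceptor genes, whose upper quartile was -2.29. Less retinal or other neural tissue is a candidate explanation, since the neurons and glia list had a median of -1.32, below the random range. The labels describe hearts, and no biological explanation of eye genes in them was tested.

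With total-count scaling, lower genes outnumbered higher genes 3.09 to 1, against 1.15 to 1 with TMM. A few abundant genes taking up reads would be a technical explanation, but without the 7 genes over 1% of a library the figure was still 2.90. What remains open is a broad difference of the abundant genes, whose median log2 ratio was 0.45 at 1000 CPM or more.

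A hypothesis was tested that sequence variants linked to foxc1a add to the 2-fold genes, since a mutant line can carry a different haplotype around the mutation. Of the 100 measured genes nearest foxc1a, by gene order on GRCz12tu, 24% were at least 2-fold apart (exact 95% interval 16.0% to 33.6%), and of all placed genes 20.2% were. The interval holds the share of all genes and also values well above it, so an excess near foxc1a was not detectable with this number of genes.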
